A study of Mus musculus with 8 samples.

How the data were processed

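Polyadenylated RNA from mouse embryonic fibroblasts (MEFs) was sequenced in 8 libraries. Per the labels, the cells were transduced with lentivirus, grown in medium with doxycycline and sorted on the fluorescent reporter encoded by the vector. RNA was extracted with Trizol and libraries were made with a stranded TruSeq mRNA kit. Of the 8 libraries, 4 carried a control empty vector (EV) and 4 a vector for wild-type YAP fused to the reporter. Within each group, replicates 1 and 2 carried GFP and replicates 3 and 4 carried mCherry, so that reporter and vector were balanced. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

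The deposited per-library table holds gene-level FPKM for each of the 8 libraries, per the file headers. TopHat, Cufflinks and the mm10 genome build are named in the submitters' processing notes, without versions. Any further scaling between libraries and the annotation release were not given in the sources used here. A second deposited table of the authors holds 1 FPKM value per pooled arm, with a p-value and a q-value for each gene, per the file headers. It was read for the authors' own calls and was used in no test. A further sheet that repeats the significant genes of that table was not used here. The number of table columns that matched no sample was 0.

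The per-library table had 48641 rows. The 49 gene identifiers that stood on more than 1 row were left out, with their 114 rows, which left 48527 genes. Of these, 48083 identifiers were found in GENCODE M21 (GRCm38, the assembly that mm10 names), which supplied biotypes and 1-based gene coordinates. Spreadsheet software had turned 27 gene symbols into dates, and identifiers were used for matching. For 90.5% of the genes in both sources, the locus in the authors' table enclosed the GENCODE gene.

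Genes with a mean FPKM of at least 1 over the 8 libraries were tested, which kept 13276 genes, of which 11188 were protein coding. Values were taken as log2(FPKM + 0.5), so fold changes are on that scale and understate the change of low genes. Linear models were fitted with limma 3.58.1 in R 4.3.3, with a trend of the variance on the mean level and empirical Bayes moderation. The vector comparison used a term for the reporter and a term for the group, and the reporter comparison was the other coefficient of that fit. The difference between reporters in the YAP minus EV effect was the interaction of the 2 terms, and effects within GFP and within mCherry were contrasts between 4 arm means with 1 shared spread. P-values were adjusted by the Benjamini-Hochberg method and the threshold was an adjusted p of 0.05. Yap1 was also tested with an exact two-sided permutation test of 4 against 4 values. A gene whose values in 4 libraries all lie on 1 side of those of the other 4 is called non-overlapping.

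The design, the alternatives and 31 gene lists (pathways, cell type markers and quality markers) were fixed before the data were examined. The 27 lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Lists share members: Amotl2, Lats2 and Ptpn14, for example, stand in both the YAP/TAZ target signature and the Hippo pathway list. Named genes were chosen by a rule fixed at the same time. It took Yap1, Wwtr1, Tead1 to Tead4, Cyr61, Ctgf, Ankrd1 and Amotl2 whatever their values, and the 8 largest increases and 8 largest decreases among non-overlapping genes past the threshold. It added up to 4 members of each list with the smallest adjusted p, and the 3 genes with the smallest p for the reporter and for the interaction. Gene models without a name were skipped in the parts on largest changes and smallest p. Genes named outside that rule are said to be so, and some genes that the rule names are not reported here. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

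Fragment counts were not used here, so the absolute depth of the libraries is unknown and no counting interval is given. FPKM sums ranged from 733152 in EV replicate 3 to 1018400 in EV replicate 1, and 1 gene, Gm3788, held 13.5% to 29.1% of the sum. Among genes with an FPKM under 0.1, the ratio between libraries takes preferred values that reflect what 1 fragment is worth. From these, depth relative to EV replicate 1 was 0.559 in EV replicate 2, 0.629 in EV replicate 3 and 0.909 in EV replicate 4. It was 1.11, 0.870, 0.962 and 0.730 in YAP replicates 1 to 4. With a limit of 0.05 in place of 0.1, EV replicate 2 gave a preferred ratio of 0.9 in place of 1.79, so its relative depth is uncertain. Another scaling of the libraries moved little: factors from median ratios ranged from 0.991 to 1.01.

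Exact zeros in the per-library table can be failed estimates. Of the tested genes, 625 had a 0 in at least 1 library, of which 303 were protein coding, and Atp5o, a subunit of the ATP synthase that all cells use, was among them. Genes at 0 in a whole arm are described as listed at 0, with each library's value and no fold change. The fitted values of Gclm, at 0 in arms of both reporters, are given only as output of the tests and are set by the pseudocount.

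The fits were tested on simulated data for 13276 genes, with 200 genes changed in each comparison. In the simulated vector comparison, 76% of genes changed by a log2 of 1 and 83% of those changed by a log2 of 2 were recovered, with 13 false calls. For the reporter the shares were 69% and 86%, within GFP 51% and 69%, within mCherry 49% and 71%, and for the interaction 16% and 47%. In the simulated list test, 1 raised list was found and 1 of the other 26 lists was also called. Some of those 26 share members with the raised list, so not all of them were fully unchanged. The simulated genes varied independently, whereas the median estimated correlation within the real lists was 0.048. That simulation therefore cannot show how often camera at the preset correlation calls lists of correlated genes. Alternatives varied the pseudocount, the filter, the scaling, the variance trend, the reporter term, a replicate block, the libraries included, and the handling of zeros and biotypes. The treatments of zeros and biotypes and a robust variance estimate were chosen after seeing the data.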

Results

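The study compared the transcriptomes of mouse embryonic fibroblasts (MEFs) that carried a control vector with those of MEFs that carried a vector for wild-type YAP, a transcriptional co-activator that is restrained by the Hippo kinase pathway and acts mainly through TEAD transcription factors. MEFs are fibroblasts cultured from mouse embryos. Expression was measured as FPKM in 8 libraries, 4 labelled EV (empty vector) and 4 labelled YAP, and each group held 2 GFP and 2 mCherry libraries. The comparison asks which genes differ when YAP is overexpressed, and the reporters give a second factor in the same samples. FPKM sums ranged from 733152 to 1018400 per library, and the absolute sequencing depth is unknown. P-values measure only the spread between these samples, which may be technical. Errors are standard deviations (SD) with n = 4 libraries unless a standard error (SE) is named.

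Yap1 itself was not higher in the libraries labelled YAP. Yap1 (ENSMUSG00000053110, chromosome 9, 7931999 to 8004596, minus strand, GRCm38) stood at 88.5, 88.4, 93.2 and 92.2 FPKM in EV replicates 1 to 4 and at 80.0, 80.7, 82.9 and 84.9 FPKM in YAP replicates 1 to 4. The means were 90.6 ± 2.49 and 82.1 ± 2.22 FPKM (SD, n = 4 each), a log2 difference of -0.14 (SE 0.049). An exact two-sided permutation test gave p = 0.0286, the smallest that 4 against 4 values can give, while the adjusted p of limma over all genes was 0.259. In the authors' deposited table Yap1 stood at 108 FPKM in the control arm and 99.96 FPKM in the YAP arm, with q = 0.721. The Yap1 transcript level thus does not check the labels, and directions below refer to the libraries as labelled.

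Known targets of YAP rose in the libraries labelled YAP. Cyr61 (Ccn1), a secreted matricellular protein and a widely used YAP target, rose from 467 ± 53.1 to 860 ± 83.0 FPKM, a log2 difference of 0.88 (SE 0.068, limma adjusted p = 0.00273). Ctgf (Ccn2), a related matricellular protein, rose from 65.3 ± 6.92 to 119 ± 9.56 FPKM (adjusted p = 0.0122), and Ankrd1, an ankyrin repeat protein of muscle and stressed cells, from 4.28 ± 0.791 to 9.62 ± 1.1 FPKM (adjusted p = 0.0170). Amotl2, an angiomotin family member that binds YAP, rose from 89.7 ± 16.5 to 358 ± 194 FPKM, a log2 difference of 1.83 (SE 0.22, adjusted p = 0.0140). In the authors' deposited table Amotl2 stood at 224 FPKM in the control arm and 597 FPKM in the YAP arm, a higher control level than in the per-library table. These genes lie on chromosome 3 (Cyr61, 145646976 to 145649981), chromosome 10 (Ctgf, 24595442 to 24598683), chromosome 19 (Ankrd1, 36111961 to 36120099) and chromosome 9 (Amotl2, 102716672 to 102733418) of GRCm38. All 4 were higher in each of the 4 libraries labelled YAP than in each of the 4 labelled EV.

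**Figure D1:**
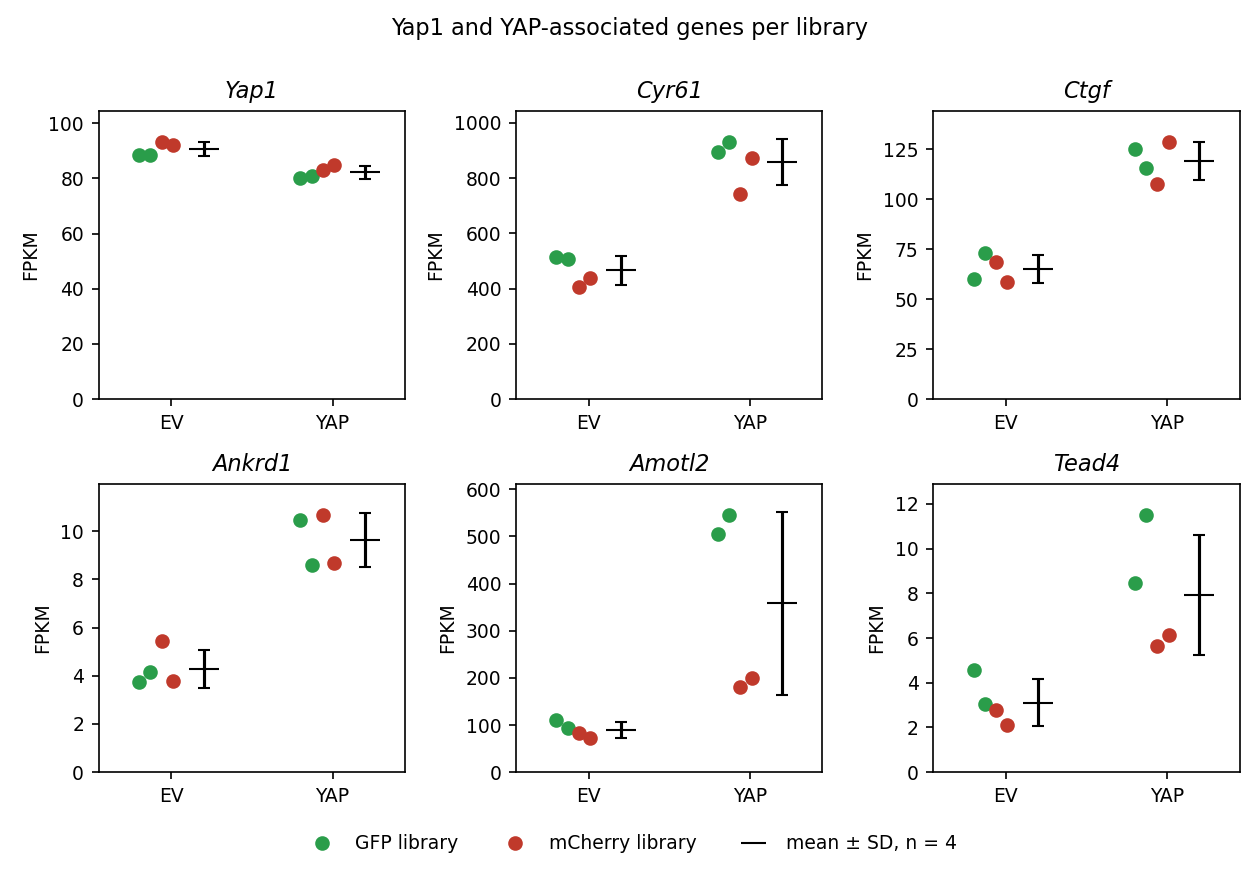
FPKM of Yap1 and 5 genes tied to YAP, on linear axes from 0, for each of the 4 EV and 4 YAP libraries; green points are GFP libraries, red points mCherry libraries, and black bars the mean ± SD. Yap1 lies between 80.0 and 84.9 FPKM in the libraries labelled YAP, below all EV libraries, while Cyr61, Ctgf, Ankrd1, Amotl2 and Tead4 lie above all EV libraries.

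Of the 22 measured members of the YAP/TAZ target signature, 6 rose, 1 fell and 15 did not pass the test, and adjusted over the list alone 10 rose and 3 fell. Besides the 4 targets above, Lats2, a Hippo kinase that restrains YAP, rose by 0.60 on the log2 scale, and Nuak2, a stress kinase named after its values were seen, by 0.99. Igfbp3, which binds insulin-like growth factors, went the other way, from 56.1 ± 12.5 to 28.1 ± 6.0 FPKM (log2 -0.98, SE 0.067, adjusted p = 0.00183). The list median was 0.25 (camera adjusted p = 0.00019; adjusted p = 0.115 with an estimated correlation). Among 28 Hippo pathway components, 4 rose, none of the other 24 passed the test, and adjusted over the list alone 7 rose (camera adjusted p = 0.000638; adjusted p = 0.115 with an estimated correlation). The 4 were Amotl2, Lats2, Amot (23.4 ± 3.13 to 33.9 ± 2.60 FPKM, adjusted p = 0.0432) and Tead4, a DNA-binding partner of YAP, which went from 3.11 ± 1.04 to 7.94 ± 2.68 FPKM (adjusted p = 0.0203). The other TEAD genes and the YAP paralog Wwtr1 (TAZ) did not pass: the log2 difference was 0.26 for Tead1 (adjusted p = 0.156), 0.023 for Tead2, 0.071 for Tead3 and -0.056 for Wwtr1.

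Over all 13276 genes, 124 were higher and 109 lower in the libraries labelled YAP at an adjusted p under 0.05 (limma), of which 27 and 25 changed by at least 2-fold. The 109 and the 25 include 3 genes listed at 0 in all 4 libraries labelled YAP, Cebpb, Ptges3l and Stab1. Their fitted changes are set by the pseudocount, and their zeros can be failed estimates. Without a correction, 1926 genes had p under 0.05. Of the calls, 122 of the higher and 103 of the lower genes were non-overlapping, and 9.46% of all tested genes were so, against 2.86% by chance. The authors' deposited table calls 365 genes higher and 349 lower, and 103 and 84 of them were also called here, with 0 opposite calls. Of the calls here, 21 higher and 25 lower were not called there, Trim2, Slc11a2, Col16a1, Tns3, Pdgfra and Ccnd1 among them. For independent lists the shared numbers would be 3.90 and 3.29, and the tables come from the same libraries. The counts depend on the libraries included: without any 1 library, 24 to 55 genes were called higher and 17 to 55 lower, and 22 to 43 of the 58 named genes that passed still did. They also depend on the fit, with 75 higher and 71 lower without a filter on level, 78 and 88 without the variance trend, and 80 and 70 without the reporter term. A replicate block, which pairs libraries by number, left 6 higher and 9 lower.

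Among named genes past the threshold and non-overlapping, the largest increase was that of Krt7, a keratin of simple epithelia, from 0.956 ± 0.341 to 6.94 ± 3.31 FPKM (log2 2.29, SE 0.34, adjusted p = 0.0263). Amotl2 came next, followed by Edn1, which encodes the vasoconstrictor endothelin 1 (0.685 ± 0.293 to 3.61 ± 1.42 FPKM, adjusted p = 0.00922), Ifitm1, an interferon-induced membrane protein (log2 1.57), and Lipg, endothelial lipase (2.38 ± 0.545 to 7.67 ± 1.00 FPKM, adjusted p = 0.00553). Trim2, a ubiquitin ligase, Ptprq, a receptor-type phosphatase, and Plcxd2 rose by 1.42, 1.42 and 1.41 on the log2 scale. Trim2 differed little in the authors' deposited table, at 14.4 and 16.1 FPKM (q = 0.856), whereas its per-library means were 3.84 and 11.5 FPKM.

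Mmp3, stromelysin 1, a secreted matrix protease, fell from 6.30 ± 1.09 to 0.853 ± 0.467 FPKM (log2 -2.38, SE 0.25, adjusted p = 0.00922). Igfbp5, another binding protein of insulin-like growth factors, fell from 114 ± 11 to 39.3 ± 4.84 FPKM (log2 -1.53, adjusted p = 0.00125). Ms4a7, a membrane protein found mainly in macrophages, fell from 7.12 ± 2.25 to 2.24 ± 1.1 FPKM, and Sod3, the extracellular superoxide dismutase, from 6.82 ± 0.60 to 2.43 ± 0.710 FPKM. Slc11a2, an iron transporter, fell by 1.67 on the log2 scale (adjusted p = 0.0485), but in the authors' deposited table the values were 50.8 and 30.1 FPKM with q = 0.0793. The fitted decreases of Cebpb, Ptges3l and Stab1 were larger still, because each was listed at 0 in all 4 libraries labelled YAP. Cebpb, a transcription factor, was listed at 22.4, 25.2, 23.9 and 25.8 FPKM in the EV libraries, Ptges3l at 9.65, 13.5, 7.77 and 7.05 FPKM, and Stab1, a scavenger receptor, at 2.11, 3.67, 3.69 and 4.24 FPKM. In the authors' deposited table these genes were not at 0 in the YAP arm, with Cebpb at 13.4 against 18.5 FPKM (q = 0.179), Ptges3l at 13.4 against 16.0 FPKM and Stab1 at 3.43 against 6.25 FPKM.

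Genes of cholesterol biosynthesis rose as a group. Of 21 measured members, 11 rose, 0 fell and 10 did not pass the test, and adjusted over the list alone 18 rose, with 18 above 0 and 0 below it at an unadjusted p under 0.05. Fdps, farnesyl diphosphate synthase, rose from 37.4 ± 2.08 to 76.7 ± 10.4 FPKM (SE 0.087 on the log2 scale, adjusted p = 0.00455). Insig1, which holds the sterol sensor SCAP in the endoplasmic reticulum, rose from 18.2 ± 1.71 to 33.1 ± 3.30 FPKM, Sqle, squalene epoxidase, from 33.2 ± 2.30 to 49.5 ± 1.79 FPKM and Cyp51, lanosterol demethylase, from 125 ± 10.7 to 182 ± 23.6 FPKM. Others that rose, named after their values were seen, include Hmgcs1, Mvk, Lss, Nsdhl and Dhcr7, enzymes of the same pathway. The list median was 0.66 (camera adjusted p = 1.29e-16; adjusted p = 0.115 with an estimated correlation), and 19 of the 21 members were above 0.

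The collagen list shifted downwards, although most of its members did not pass the test. Of 23 measured collagen genes, 8 fell, 1 rose and 14 did not pass, and adjusted over the list alone 11 fell and 1 rose (camera adjusted p = 0.000685; adjusted p = 0.234 with an estimated correlation). All 3 classical chains of collagen VI, a microfibrillar collagen, fell: Col6a3 from 174 ± 5.56 to 91.3 ± 10.5 FPKM (log2 -0.94, SE 0.068, adjusted p = 0.0023), Col6a2 from 284 ± 15.1 to 192 ± 20.5 FPKM and Col6a1 from 308 ± 22.7 to 220 ± 15.3 FPKM. Col16a1 fell by 0.53 on the log2 scale, but was not called in the authors' deposited table (q = 0.110). The list median was -0.070, since 10 members lay above 0 and 13 below.

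Other matrix genes moved both ways. Of 38 matrix glycoprotein genes, 7 fell and 3 rose, and adjusted over the list alone 12 fell and 8 rose, and the list did not pass camera (adjusted p = 0.0558) but did by fry (adjusted p = 0.0425). It also passed camera without a filter on level (adjusted p = 0.0181), with quantile normalization (0.00391), without EV replicate 2 (0.0224) or YAP replicate 2 (0.0213) and with mCherry libraries alone (0.0252). With an estimated correlation it did not pass (camera adjusted p = 0.473). Spp1, the secreted phosphoprotein osteopontin, fell from 1372 ± 50.8 to 619.6 ± 112 FPKM (log2 -1.16, SE 0.089, adjusted p = 0.00273), Smoc2, a matricellular calcium-binding protein, from 44.4 ± 1.91 to 18.4 ± 1.94 FPKM and Tgfbi from 135 ± 12.1 to 81.5 ± 7.67 FPKM. Efemp1, fibulin 3, rose from 68.7 ± 1.09 to 154 ± 7.75 FPKM (log2 1.15, SE 0.058, adjusted p = 0.000689). Of 19 proteoglycan genes, 2 fell and 0 rose, and adjusted over the list alone 8 fell and 2 rose; at an unadjusted p under 0.05, 3 were above 0 and 9 below. Lum, the collagen-binding lumican, fell from 50.9 ± 4.66 to 20.6 ± 4.86 FPKM, and Sdc3, a syndecan, from 65.7 ± 2.36 to 41.3 ± 5.95 FPKM (camera adjusted p = 0.00326 for the list; adjusted p = 0.177 with an estimated correlation). Among 25 matrix proteases and inhibitors, 2 rose, among them Adamts5, an aggrecanase (22.9 ± 1.03 to 50.7 ± 4.64 FPKM), and Mmp3 fell, while adjusted over the list alone 8 rose and 5 fell. That list did not pass (camera adjusted p = 0.370), and its median of 0.043 and its mean of -0.042 differed in sign.

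Secreted growth factors and antagonists shifted upwards, with 4 of 47 members up, 3 down and a median of 0.16 (camera adjusted p = 0.0331; adjusted p = 0.117 with an estimated correlation). Adjusted over the list alone, 12 rose and 5 fell. Grem1, an antagonist of bone morphogenetic proteins, fell from 11 ± 0.619 to 5.42 ± 0.273 FPKM (adjusted p = 0.00483). Csf1, the macrophage colony-stimulating factor, rose from 135 ± 13.2 to 227 ± 19.3 FPKM and was the 1 of 17 chemokines and cytokines that passed, also adjusted over the list alone with 1 rise and 1 fall (camera adjusted p = 0.649). Of 21 p53 target genes, 1 rose, Plk2, a polo-like kinase (40.3 ± 1.42 to 65.9 ± 7.19 FPKM), and adjusted over the list alone 4 rose (camera adjusted p = 0.00326; adjusted p = 0.115 with an estimated correlation). Of 25 contractile and serum response factor target genes, 2 fell, Mylk, the myosin light chain kinase (4.77 ± 0.306 to 2.05 ± 0.312 FPKM), and Cnn1, calponin 1 (43.1 ± 3.97 to 21.5 ± 6.66 FPKM). Adjusted over that list alone 7 fell (camera adjusted p = 0.0432; adjusted p = 0.569 with an estimated correlation). The contractile list did not pass without EV replicate 1 (camera adjusted p = 0.0732), EV replicate 2 (0.132), YAP replicate 1 (0.117, with a median of 0.0092), YAP replicate 2 (0.0601) or YAP replicate 3 (0.159), nor without the reporter term (0.0678). The growth factor list did not pass without EV replicate 1 (0.0509), YAP replicate 2 (0.0601) or YAP replicate 4 (0.0760).

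Interferon-stimulated genes were lower in the libraries labelled YAP. Of 26 measured members 24 lay below 0, 2 fell past the threshold over all genes and 11 fell adjusted over the list alone. The median was -0.53 (camera adjusted p = 2.31e-10; adjusted p = 0.177 with an estimated correlation). Oasl2, an antiviral oligoadenylate synthetase-like protein, fell from 47.0 ± 5.51 to 19.6 ± 5.55 FPKM (log2 -1.28, SE 0.20, adjusted p = 0.0285), and Isg15, a ubiquitin-like protein, from 272 ± 81.4 to 166 ± 52.9 FPKM (adjusted p = 0.0415). Gbp3 and Stat2 had log2 differences of -0.71 and -0.55 and did not pass (adjusted p = 0.0574 and 0.0946). The interferon-stimulated list was also lower in mCherry than in GFP libraries, with a median of -0.36 (camera adjusted p = 8.63e-08; adjusted p = 0.522 with an estimated correlation).

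Markers of another cell type moved with the groups. Of 17 measured macrophage and leukocyte markers, 14 lay below 0 in the libraries labelled YAP, 2 fell and 15 did not pass, and adjusted over the list alone 4 fell (camera adjusted p = 0.00264; adjusted p = 0.234 with an estimated correlation). C1qa and C1qc, chains of complement C1q that macrophages make, fell from 48.4 ± 12.3 to 24.6 ± 6.49 FPKM and from 44.8 ± 8.18 to 24.0 ± 5.69 FPKM (adjusted p = 0.0169 and 0.0353). The list median was -0.29, beside falls of Spp1 and Ms4a7, which macrophages also express. It was -0.47 within GFP and -0.13 within mCherry libraries, and with mCherry libraries alone the list did not pass (camera adjusted p = 0.177). Of the other cell type lists, 18 fibroblast genes had a median of 0.032 and 1 fall, Pdgfra, a platelet-derived growth factor receptor (25.7 ± 2.83 to 17.3 ± 0.415 FPKM), with 4 rises and 2 falls adjusted over the list alone (camera adjusted p = 0.652). In the authors' deposited table Pdgfra stood at 60.7 FPKM in the control arm and 46.3 FPKM in the YAP arm (q = 0.421). Of 11 chondrocyte and bone markers 0 passed over all genes or adjusted over the list alone, 5 were below 0 and 0 above it at an unadjusted p under 0.05, and the list was lower (median -0.39, camera adjusted p = 0.00611; adjusted p = 0.117 with an estimated correlation). Of 8 adipocyte markers 1 rose, the desaturase Scd1 (38.6 ± 1.30 to 58.8 ± 9.42 FPKM), also adjusted over the list alone (camera adjusted p = 0.961). Of 5 skeletal muscle markers 0 passed over all genes, adjusted over the list alone or at an unadjusted p under 0.05 (camera adjusted p = 0.746).

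The remaining cell type lists had too few measured members for a list test. Of 3 epithelial markers Krt7 rose, and Krt19 stood at 11.2 ± 4.36 and 22.5 ± 8.45 FPKM (adjusted p = 0.132), with 2 rises adjusted over the list alone. Of 3 endothelial markers Erg, an ETS transcription factor, fell from 17.3 ± 1.57 to 10.3 ± 0.874 FPKM, also adjusted over the list alone. Of 4 neural and glial markers 2 rose, Stmn2, a microtubule regulator of neurons (7.49 ± 0.908 to 16.5 ± 1.46 FPKM, adjusted p = 0.00365), and Map2, a microtubule-associated protein (13.1 ± 1.22 to 21.4 ± 1.15 FPKM), and the same number rose adjusted over the list alone. Of the pluripotency genes 2 were measured. Sox2 stood at 1.98 ± 0.580 and 0.970 ± 0.399 FPKM (adjusted p = 0.165) and Klf2 at 15.9 ± 1.62 and 19.4 ± 2.34 FPKM (adjusted p = 0.339), and adjusted over the list alone Klf2 rose and Sox2 fell.

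Several broad lists shifted without any member passing over all genes. Immediate early and AP-1 genes had a median of 0.24 over 23 members, with 3 rises adjusted over the list alone and 9 members above 0 and 0 below at an unadjusted p under 0.05 (camera adjusted p = 0.00201; adjusted p = 0.473 with an estimated correlation). Ribosomal protein genes had a median of 0.12 over 25 members, with 0 passing adjusted over the list alone and 8 above 0 at an unadjusted p under 0.05 (camera adjusted p = 0.00188; adjusted p = 0.115 with an estimated correlation). For 22 mitochondrial respiratory chain genes the median was 0.10, with 0 passing adjusted over the list alone and 3 above 0 at an unadjusted p under 0.05 (camera adjusted p = 0.00716; adjusted p = 0.115 with an estimated correlation). DNA replication genes had a median of -0.14 over 26 members, with 0 passing adjusted over the list alone, and 1 above and 3 below 0 at an unadjusted p under 0.05 (camera adjusted p = 0.0266; adjusted p = 0.234 with an estimated correlation). With quantile normalization the ribosomal list (median 0.064, camera adjusted p = 0.170) and the respiratory chain list (median 0.070, adjusted p = 0.0709) did not pass. The replication list did not pass without EV replicate 1 (camera adjusted p = 0.0945), YAP replicate 1 (0.0526), YAP replicate 2 (0.0601) or YAP replicate 4 (0.0536), and the immediate early list did not without YAP replicate 4 (0.0536). Of 27 mitosis genes 0 passed over all genes, adjusted over the list alone or at an unadjusted p under 0.05 (camera adjusted p = 0.652).

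The other lists did not pass. Of 24 glycolysis and hypoxia genes Adm, which encodes the vasodilator adrenomedullin, rose from 29.4 ± 6.45 to 64.9 ± 6.0 FPKM, and 2 rose adjusted over the list alone (camera adjusted p = 0.278). Of 24 genes of the ER stress and ATF4 response Psat1, an enzyme of serine synthesis, rose from 97.2 ± 0.885 to 127 ± 9.90 FPKM, and 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.171). The median of that list was -0.027 and its mean 0.014. Of 10 Wnt targets Ccnd1, which encodes cyclin D1, rose from 78.5 ± 4.76 to 116 ± 23.8 FPKM, also adjusted over the list alone (camera adjusted p = 0.649). The authors' deposited table did not call Ccnd1 (q = 0.0859). Of 18 TGF-beta targets 2 rose, Ctgf among them, and Tgfbi and Ltbp2 fell, Ltbp2 from 62.5 ± 1.54 to 35.2 ± 5.41 FPKM, and adjusted over the list alone 3 rose and 2 fell (camera adjusted p = 0.649). Of 23 focal adhesion genes Tns3, a tensin, fell from 52.1 ± 1.33 to 40.2 ± 2.25 FPKM, and adjusted over the list alone 1 rose and 1 fell (camera adjusted p = 0.536). Tns3 was not called in the authors' deposited table (q = 0.185). In all, 15 of 27 lists passed camera at the preset correlation, 8 up and 7 down, and 13 passed fry. With an estimated correlation 0 passed, and 8 had an unadjusted p under 0.05.

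**Figure D2:**
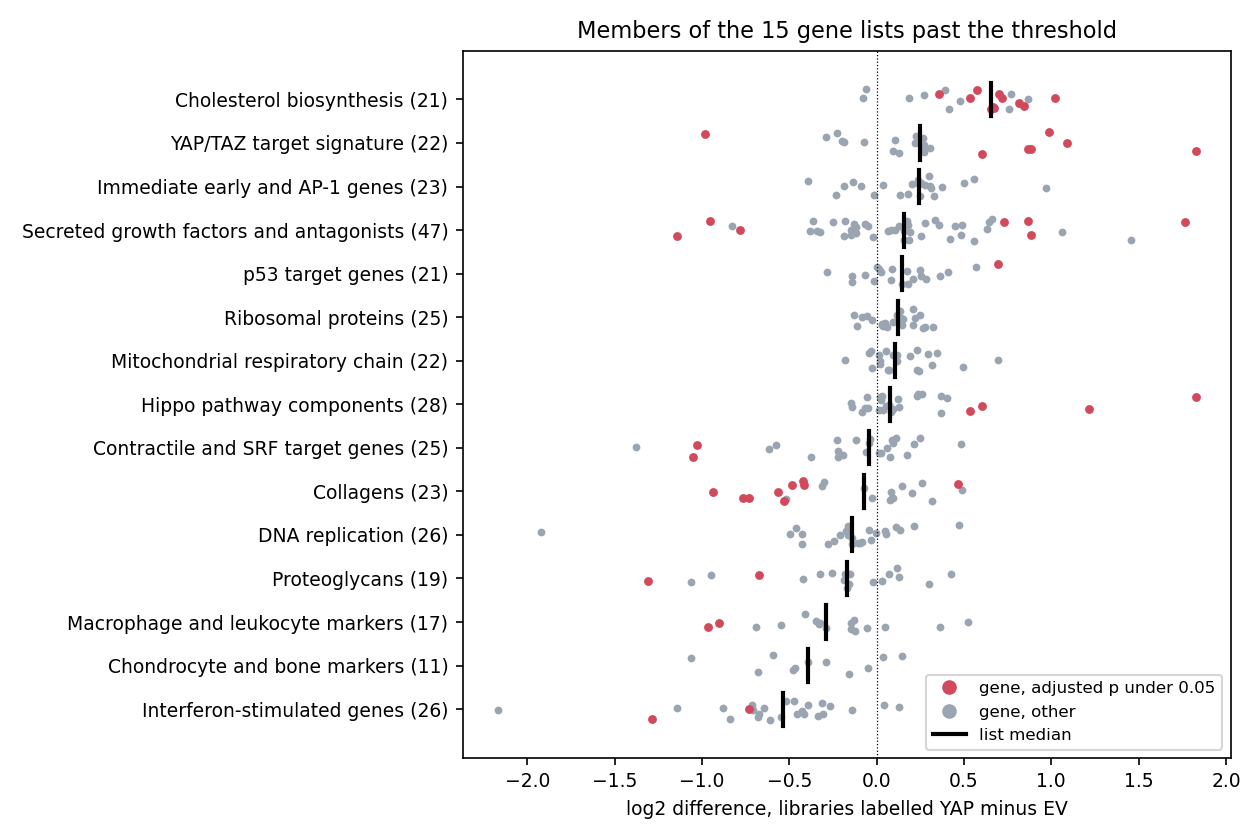
Log2 difference (libraries labelled YAP minus EV, log2(FPKM + 0.5) scale) of each measured member of the 15 lists that passed camera at the preset correlation, with the number of members in brackets. Red points are genes past the threshold over all genes, grey points the others, and black bars list medians, from 0.66 for cholesterol biosynthesis to -0.53 for interferon-stimulated genes.

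The reporter comparison asks whether GFP and mCherry libraries differ whatever the vector. Macrophage and leukocyte markers were higher in the mCherry libraries: 17 of 17 lay above 0, the median was 0.60, 12 passed adjusted over the list alone, and over all genes 0 passed, with 13 above 0 and 0 below at an unadjusted p under 0.05 (camera adjusted p = 8.08e-11; adjusted p = 0.272 with an estimated correlation). Interferon-stimulated genes were lower, with a median of -0.36 and 3 falls adjusted over the list alone, while over all genes 0 passed and 8 were below 0 at an unadjusted p under 0.05 (camera adjusted p = 8.63e-08; adjusted p = 0.522 with an estimated correlation). Immediate early genes had a median of -0.29 (camera adjusted p = 7.61e-06; adjusted p = 0.522 with an estimated correlation) and mitosis genes a median of 0.17 (camera adjusted p = 0.000255; adjusted p = 0.405 with an estimated correlation). Shifts upwards also passed for proteoglycans (median 0.18), matrix glycoproteins (0.091), contractile genes (0.11) and the respiratory chain (0.081), with camera adjusted p = 0.405, 0.522, 0.532 and 0.405 with an estimated correlation. The respiratory chain list holds Atp5o, listed at 0 in all GFP libraries, and its mean was 0.44. In all 8 lists passed at the preset correlation and 2 by fry, the macrophage markers and the respiratory chain. With an estimated correlation 0 passed and 3 had an unadjusted p under 0.05.

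Single genes that differed by reporter were few, with 12 past the threshold (limma) and 1404 at an unadjusted p under 0.05. Of the 12, 7 were listed at 0 in at least 1 library, and with zeros as missing 4 genes passed. The 3 with the smallest p were Atp5o, a subunit of the ATP synthase, Jmjd6, a hydroxylase, and Gadl1, a decarboxylase, and all were listed at 0 in the 4 GFP libraries. In the mCherry libraries, EV replicates 3 and 4 and then YAP replicates 3 and 4, Atp5o stood at 169, 144, 167 and 154 FPKM, Jmjd6 at 41.8, 43.4, 40.2 and 31.6 FPKM, and Gadl1 at 16.0, 23.8, 24.7 and 28.6 FPKM. In the authors' deposited table the control and YAP arms, which pool both reporters, stood at 168 and 189 FPKM for Atp5o. They were 32.0 and 27.9 FPKM for Jmjd6, and 18.1 and 24.4 FPKM for Gadl1. The zeros can thus be failed estimates, and on their own they show no difference by reporter.

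Within reporters, the YAP minus EV difference was past the threshold for 172 genes in GFP (89 higher, 83 lower) and 53 in mCherry (32 higher, 21 lower), and 34 genes were in both sets, 30 of them in the same direction. These counts depend on the libraries: without any 1 library, 54 to 97 passed within GFP, and within mCherry 29 passed without EV replicate 3, 33 without YAP replicate 4 and 21 without EV replicate 4, YAP replicate 1 or YAP replicate 2. Fits on the GFP libraries alone called 7 genes higher and 13 lower, and fits on the mCherry libraries alone 9 and 13. Cyr61 had a log2 difference of 0.83 in GFP and 0.93 in mCherry (SE 0.092), Ctgf of 0.85 and 0.89, Ankrd1 of 1.17 and 1.01 and Tead4 of 1.30 and 1.13. Amotl2 had 2.37 in GFP and 1.29 in mCherry (SE 0.13), and this difference of -1.08 did not pass over all genes (limma adjusted p = 0.233). The difference between reporters passed for 9 genes, of which 7 were listed at 0 in at least 1 library, and 1302 had an unadjusted p under 0.05. That count was 23 without a filter on level and 2 with zeros as missing. It was 36, 35 and 23 without EV replicates 1, 2 and 3, and 34, 29, 38 and 23 without YAP replicates 1 to 4. The 3 named by the rule were Gclm, a subunit of the enzyme that makes glutathione's precursor, Kat2b, an acetyltransferase, and Dlgap5, a spindle protein. Gclm was listed at 0 in both mCherry EV libraries and both GFP YAP libraries, and at 66.6, 62.8, 45.2 and 41.7 FPKM in the others. Kat2b stood at 27.6 and 30.7 FPKM in GFP EV libraries, 7.32 and 7.36 in mCherry EV libraries, 8.44 and 7.28 in GFP YAP libraries and 28.7 and 26.0 FPKM in mCherry YAP libraries. In the authors' deposited table it stood at 28.1 FPKM in the control arm and 29.4 FPKM in the YAP arm.

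The libraries separated by both factors. Over 12651 genes with no 0, the first principal component (22.1% of the variance) placed the EV libraries from -26.4 to -8.08 and the YAP libraries from 9.98 to 19.0. The second (17.7%) placed the GFP libraries at 4.77 to 20.1 and the mCherry libraries below 0. Over the same genes, Pearson correlations between libraries were 0.967 to 0.979 within groups and 0.963 to 0.977 between them. With the genes that have zeros included, they were 0.909 to 0.935 over all pairs.

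**Figure D3:**
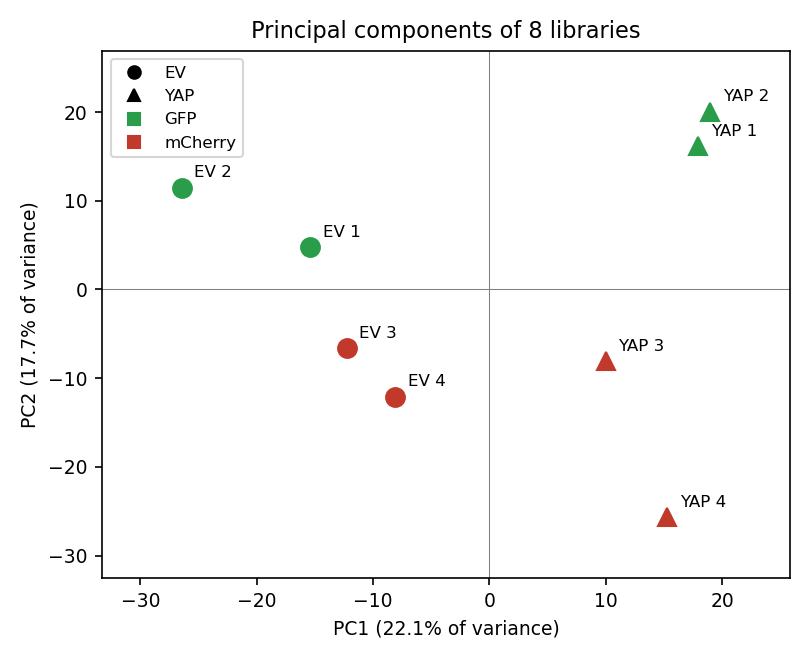
First and second principal components of log2(FPKM + 0.5) over 12651 genes with no 0, as unitless scores. Circles are EV and triangles YAP libraries, green GFP and red mCherry; EV libraries lie at -8.08 or below on the first axis, YAP libraries at 9.98 or above, and the GFP and mCherry libraries lie on opposite sides of 0 on the second axis.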

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

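The tests of exchanged groups, of uncounted vector transcripts, of protein coding genes at 0 and of the C1q genes and the whole fall of Spp1 against the other macrophage markers were chosen only after the results were seen, and so were the counts over other splits of the libraries.

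Yap1 was not higher in the libraries labelled YAP although known targets rose. An exchange of the groups is argued against, since 4 of 4 libraries labelled YAP had Ankrd1, Ctgf, Cyr61 and Amotl2 all above every library labelled EV, where an exchange would put them lower. Vector transcripts not counted at the mouse Yap1 gene remain open: the Yap1 log2 difference of -0.14 could come from the endogenous gene alone, and no value here reads the vector, which is what keeps it open. A biological fall of endogenous Yap1 under YAP overexpression is also open and untested, with adjusted p = 0.259 over all genes.

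Among the tested genes, 154 were listed at 0 in all 4 libraries of a group, 82 in EV and 72 in YAP. If failed estimates in the per-library table were the cause, the authors' pooled table would show expression in both arms. Over the 129 genes with a value above 0 there in the other arm, 37.21% reached 0.25 of that value, between the bounds set in advance. Among 43 protein coding genes 93.02% (40) did, Cebpb, Ptges3l and Stab1 included, so a failed estimate is a candidate explanation for these. Only 8 of 86 others did. No bound was set for those alone, so they stay undecided. For 103 of the 154 genes the pooled value of the arm listed at 0 was also 0. A biological loss of Cebpb, Ptges3l or Stab1 would need near 0 in the pooled arm, where they stood at 13.4, 13.4 and 3.43 FPKM.

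Macrophage genes and the abundant Spp1 were lower in the libraries labelled YAP. If fewer macrophages accounted for the fall of C1qa, C1qb and C1qc (median -0.90), the other 14 markers would fall about as much. Their median was -0.15 (SD 0.29), with 3 of them above 0. But C1qa, C1qb and C1qc were the markers of this list that fell most. The others therefore had to fall less, and this comparison cannot decide. Fewer macrophages do not account for the whole fall of Spp1 (-1.16), because the median of all 17 markers was -0.29 (SD 0.39), with -0.47 within GFP and -0.13 within mCherry libraries. A part played by macrophage content in Spp1 cannot be told apart from a change in the fibroblasts: between reporters Spp1 differed by 0.26 (SE 0.089), below but close to the bound set in advance, 0.5 of the markers' median, which was 0.30. Regulation of the C1q genes and Spp1 by YAP may be involved and was not tested.

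A library lay far from the other 3 of its group for 15 of 276 groups of named genes, or 5.43%, where chance gives about 5%. In EV replicate 1 this was Cnn1 (37.1 FPKM). In EV replicate 3 it was Ms4a7 (10.5), Tpm2 (763.7), Aurka (17.9), Hspa5 (331.5) and Egfl7 (12.1, the others at 0). In EV replicate 4 it was Trim2 (4.52), Fdps (40.5), Pfkp (11.4, the others at 0) and Ltbp2 (64.8). In the YAP group it was Egfl7 (26.2, the others at 0) and Stmn2 (14.3) in replicate 2, Des (2.83) in replicate 3, and Oasl2 (11.4) and Stat2 (13.8) in replicate 4, all in FPKM.

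The YAP minus EV difference differed between reporters (mCherry minus GFP, log2) by 3.65 for Kat2b and by 1.97 for Dlgap5 (limma adjusted p = 0.00215 and 0.00951). In the authors' deposited table Kat2b stood at 28.1 FPKM in the control arm and 29.4 FPKM in the YAP arm, near its higher libraries. Its low values lie in the same libraries where Gclm is listed at 0, so a failed estimate is a candidate explanation for Kat2b too. For Gclm the fit returned 13.5, which is set by the pseudocount, because 4 libraries are listed at 0, and measures no change. Among lists, the median difference was 0.23 for contractile genes, -0.29 for cholesterol biosynthesis, 0.22 for glycolysis and hypoxia genes, 0.13 for the ER stress and ATF4 response and 0.35 for immediate early genes. These passed camera at the preset correlation (adjusted p from 0.00553 to 0.0162) and not with an estimated one (adjusted p from 0.515 to 0.620), and fry called 0 lists, with 1 at an unadjusted p under 0.05 by camera with an estimated correlation.

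For the genes of the vector comparison, 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, called as many as 233 genes. The highest other called 12. This argues against chance only if the 8 libraries are separate units, which the labels do not say, and 1 of 35 is the smallest share possible. For lists 1 of 35 reached 15, and another reached 13. That other split differs from the real one only by an exchange of EV replicate 3 and YAP replicate 2. It thus keeps part of the vector difference and cannot show how many lists chance alone would call. The number of lists called stays a weak sign on its own. For the reporter comparison 2 of 35 splits called at least 12 genes, and the other was the split by vector with 150, which follows the other factor of the design. The 33 splits other than by vector or reporter called at most 6, and some of them differ from the vector split by only 1 library of each group. Among genes with no 0, in fits without a vector term, the split by reporter called 4 genes and one of those 33 called 5, so the higher count rests on genes listed at 0. Counted over all 35, chance is not excluded for the reporter.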

How the results depend on the processing

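The handling of zeros, the restriction to protein coding genes and the robust variance estimate were chosen after seeing the data. The main counts were 124 genes higher and 109 lower in the libraries labelled YAP, 172 within GFP, 53 within mCherry, 12 for the reporter, 9 for the interaction and 15 lists. Pseudocounts, scalings, a mean FPKM of at least 5 and robust variances kept the vector counts within 1.5 times, at 108 to 124 higher and 98 to 110 lower, and so did zeros as missing (126 and 114) and protein coding genes above 0 everywhere (144 and 128). Without a filter 75 were higher and 71 lower (interaction 23). Without the variance trend 78 were higher and 88 lower, 110 passed within GFP, 32 within mCherry and 15 for the interaction. Without the reporter term the counts were 80 and 70, and with at least a 2-fold change 27 and 25. With GFP libraries alone they were 7 and 13 (9 lists), and with mCherry libraries alone 9 and 13; fewer samples enter those fits. A mean FPKM of at least 5 gave 4 genes for the interaction. With zeros as missing the reporter gave 4 genes and the interaction 2, and with protein coding genes above 0 everywhere 5 and 2; those genes with zeros are then gone. With an estimated correlation 0 lists passed. For the rest the cause was not tested. Leaving out 1 library gave 24 to 55 higher, 17 to 55 lower, 54 to 97 within GFP, 21 to 61 within mCherry, 12 to 38 for the interaction, 10 to 14 for the reporter and 12 to 15 lists. Without EV replicates 1 to 4 in turn the higher and lower counts were 29 and 24, 27 and 17, 33 and 34, and 41 and 28; without YAP replicates 1 to 4 they were 49 and 39, 24 and 24, 55 and 51, and 49 and 55. With a replicate block, 6 genes were higher and 9 lower, and 14 of the 15 lists passed. Whether libraries of the same number are paired is not known from the labels. They correlated by 0.0080, 0.050, -0.051 and 0.080 in their deviations from group means, and 2 of 4 EV libraries correlated best with their own number. These values are too few to decide it. Of 58 named genes called, 22 to 43 still passed without 1 library, and none of them changed direction. Changed lists are given with their median log2 difference. Without a filter the matrix glycoproteins gained a call (-0.083) and the adipocyte markers turned without one (0.083). With a mean FPKM of at least 5, growth factors (0.12) and contractile genes (-0.039) lost theirs. With quantile normalization ribosomal (0.064) and respiratory chain genes (0.070) lost their call, matrix glycoproteins gained one (-0.074), and fibroblast (0.038) and adipocyte markers (-0.20), called in neither, turned in the direction of the test. Contractile genes lost their call without the reporter term (-0.044), with a replicate block (-0.044) and with protein coding genes above 0 everywhere (-0.044), where DNA replication (-0.14) did too. With GFP libraries alone the call was lost by growth factors (0.012), p53 targets (0.051), immediate early (0.037), ribosomal (0.13), respiratory chain (0.054) and chondrocyte and bone genes (-0.34); mitosis (0.015), glycolysis (-0.00458), ER stress (-0.16) and skeletal muscle genes (-0.017), called in neither, turned. With mCherry libraries alone the call was lost by Hippo components (0.028), proteoglycans (-0.11), growth factors (0.15), contractile (-0.013), DNA replication (-0.029) and macrophage genes (-0.13), and gained by matrix glycoproteins (-0.11), glycolysis (0.10) and ER stress genes (0.16); proteases (0.0054), chemokines (0.14), Wnt (-0.031) and TGF-beta targets (-0.00415) and adipocyte markers (-0.33), called in neither, turned. Without 1 library, medians ranged from -0.11 to -0.035 for matrix glycoproteins, 0.058 to 0.17 for growth factors, -0.11 to 0.0092 for contractile genes, -0.17 to -0.12 for DNA replication, 0.16 to 0.31 for immediate early genes and -0.074 to 0.065 for ER stress, each with a changed call, and from -0.011 to 0.070 for mitosis, 0.011 to 0.090 for fibroblast genes and -0.38 to 0.0044 for adipocyte markers, where only the direction of a test not called turned. The fitted value of Gclm turned to 6.46 with mCherry libraries alone, since its zeros lie in opposite arms of the reporters; the pseudocount sets it and it measures no change. The Yap1 difference stayed between -0.17 and -0.13. Depth is known only in relative terms, so it bounds no value here.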

Other observations

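The gene groups in the next paragraphs were noticed and chosen after the values were seen, and the counts over all their measured members are given. The test of directions across reporters was written before its result was seen.

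Of 11 measured genes of fatty acid synthesis and desaturation, 5 rose, 0 fell and 6 did not pass the test in the libraries labelled YAP: Acly, which makes cytosolic acetyl-CoA (57.5 ± 0.690 to 75.7 ± 3.12 FPKM), the desaturases Scd1, Scd2 (194 ± 5.86 to 276 ± 24.0 FPKM), Fads1 and Fads2 (88.5 ± 9.25 to 129 ± 13.7 FPKM). Of those 6, 5 lay above 0, Fasn among them (log2 0.35, limma adjusted p = 0.117). Of 6 class 3 semaphorins, secreted guidance proteins, 4 rose, from Sema3f at a log2 of 0.30 to Sema3e at 0.83, and 2 lay above 0 without passing. Of 11 tubulin genes, Tubb4b-ps1, a pseudogene by its name, among them, 4 rose, Tubb2b the most (54.9 ± 3.02 to 87.9 ± 8.44 FPKM, adjusted p = 0.00721). None fell, and 7 did not pass, 4 above 0 and 3 below it. Of 16 annexin and caveolar genes 5 rose: Anxa3 (279 ± 16.9 to 493 ± 23.6 FPKM), Anxa2 and its partner S100a10 (171 ± 13.9 to 291 ± 22.1 FPKM), Cav1, caveolin 1 (462 ± 26.8 to 703 ± 62.2 FPKM), and Sdpr, a cavin. In the last group 0 fell and 11 did not pass, 8 above 0 and 3 below it, and 2 of those 11 changed sign with the scaling.

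Of 5 measured genes of the endothelin axis, 1 rose, 2 fell and 2, the converting enzymes Ece1 and Ece2, did not pass. Edn1 rose while its receptors Ednra (10.2 ± 0.991 to 6.04 ± 1.07 FPKM, adjusted p = 0.0423) and Ednrb (12.7 ± 1.38 to 7.17 ± 0.550 FPKM, adjusted p = 0.0169) fell. Of 6 basement membrane collagens 3 fell, 1 rose and 2 lay above 0 without passing. Col4a1 and Col4a2, which form 1 heterotrimer, fell from 183 ± 8.25 to 137 ± 9.79 FPKM and from 166 ± 5.12 to 124 ± 6.96 FPKM, Col18a1 fell by 0.76 on the log2 scale, and Col4a5 rose from 38.9 ± 1.85 to 54.2 ± 7.01 FPKM. Single genes for secreted proteins, which form no group that was tested, fell, namely Ptn, pleiotrophin (1558 ± 226 to 983 ± 56.6 FPKM, adjusted p = 0.0240), Mgp, matrix Gla protein (926 ± 39.1 to 441 ± 129 FPKM), and Tnn, tenascin W (57.6 ± 10.4 to 23.0 ± 6.65 FPKM). Other single genes, not all for secreted proteins, rose: Lox, lysyl oxidase, from 539 ± 16.4 to 726 ± 39.0 FPKM, Ptx3, a pentraxin, from 60.2 ± 6.03 to 157 ± 7.42 FPKM (adjusted p = 0.00140), and Msln, mesothelin, from 9.21 ± 1.64 to 23.4 ± 4.92 FPKM (adjusted p = 0.000764).

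A hypothesis was that the YAP minus EV differences are shared by both reporter constructs. The GFP and mCherry libraries have separate controls, so agreement between them is not built in. Of the 200 genes with the smallest p in the GFP libraries alone, 79.0% (158) had the same direction in the mCherry libraries, above the 75% set in advance, and of the 200 taken from mCherry 77.5% did in GFP. Over all 12651 genes with no 0 the share was 55.8% and Pearson's r across genes, which are not independent replicates, 0.18. This is consistent with a shared response in the genes that changed most, beside much spread in the others.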
